A study of Mus musculus with 5 samples.

How the data were processed

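Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on gliomas that a PDGFB virus induced in the mouse brain, 25 days after injection of the virus. Olig2cKO tumours carried floxed Olig2 alleles in addition to the alleles of the control tumours, per the labels. The 5 libraries were Olig2 in control tumours, acetylated lysine 27 of histone H3 (H3K27ac) in each genotype, and trimethylated lysine 4 of histone H3 (H3K4me3) in each genotype. Each group had 1 library. Olig2 ChIP was analysed here in control tumours, so the loss of Olig2 in the Olig2cKO libraries was not checked from these data.

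CASAVA, Bowtie2 and MACS are named, for the mouse build mm9, per the submitters' processing notes, which give no versions or settings in the sources used here. Whether an input library was used for peak calling is not given in the sources used here. Each deposited list holds the peaks of 1 library, with a start, an end and a score that the authors' peak caller assigned to each peak. The lowest score in every list lay between 50 and 50.02, which is where −10 times the base 10 logarithm of a peak p-value stands at 1e-05, a scale that MACS writes by default. The scores are the authors' own and are not scaled between libraries, so they served only to rank, filter or group peaks inside a list. The number of reads behind each list is not given in the sources used here, so the depth is unknown, and a longer list can come from a deeper or cleaner library.

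The build was checked against the lengths of the mm9 chromosomes in GenomeInfoDb 1.38.1. On the 20 chromosomes compared (1 to 19 and X), 0 had a peak beyond its mm9 length, while 10 had a peak beyond the last gene of the GRCm38.p6 table of gene names. Gene positions on mm9 were not used here, and no position was carried from one build to another. Peaks are therefore given by position, no peak is assigned to a gene, and the comparison of gene lists that had been planned was not run. Positions are on mm9 and count from 1.

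A peak was shared when it overlapped a peak of the other list by at least 1 bp. A peak without such a partner is called genotype-only (control-only or Olig2cKO-only), which means that no overlapping peak was listed, not that the mark was absent. Overlaps were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and were checked against bedtools 2.31.1 in 4 comparisons. The counts were identical at 1 bp overlap. When peaks up to 1 kb apart were counted as shared, 1 comparison differed by 1 peak, and the difference went away when bedtools was given 1 bp more. On simulated lists made from the 56600 control H3K27ac peaks, with 70.0% of the peaks given a partner, 70.0% were recovered. An odds ratio of 0.5 simulated for 60000 peaks in 10 strata was recovered as 0.506, where the ratio without strata was 0.311. All 50 domains placed among 200 simulated peaks were found.

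Shares carry exact (Clopper-Pearson) binomial intervals at 95%, from scipy 1.17.1. The intervals cover counting error only, and neighbouring peaks are not independent. With 1 library per group there is no replicate check of any difference between genotypes, no test between genotypes was made, and no p-value is given. Overlaps were set beside 1000 random placements of the peaks on their own chromosomes, and beside 1000 shifts of each peak by 100 kb to 1 Mb, the second added after the data were seen. Random placement does not avoid gaps or repeats.

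Olig2-bound means that a histone peak overlapped an Olig2 peak of control tumours. A promoter-type H3K27ac peak overlapped an H3K4me3 peak of the same genotype, and a distal one did not. Bound and unbound, or promoter-type and distal, peaks of a list were compared within 10 score classes and 10 width classes of equal size with the Mantel-Haenszel odds ratio of having no partner (statsmodels 0.14.6), as a description of these libraries. An odds ratio below 1 means that the feature went with fewer genotype-only peaks. Distal H3K27ac peaks at most 12.5 kb apart were stitched into domains, and a domain needed 3 peaks. Windows of 1 Mb were filled by the middle of each peak. Figures were drawn with matplotlib 3.10.9.

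Before the data were examined, the regions to be named were fixed as the 5 genotype-only peaks with the highest score for each mark and direction, the 5 highest Olig2 peaks, the 5 longest domains and the 5 longest genotype-only domains of each genotype, and the 5 windows with most genotype-only peaks for each mark and direction. Ties between windows were taken in chromosome order. The alternatives fixed at the same time were the upper 50% of each list by score, lists cut to equal length, an overlap of 50% of the shorter peak, peaks up to 1 kb apart counted as shared, peaks within 1 kb merged inside each list, a stitching distance of 5 kb, and numbered chromosomes alone. The alternatives added later were the upper 50% of a list against the whole other list, and the Olig2 overlaps without Olig2 peaks that all 4 histone lists match in position within 300 bp.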

Results

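The 5 peak lists describe where the transcription factor Olig2, which marks the oligodendrocyte lineage, and the histone marks H3K27ac and H3K4me3 lay in PDGFB-induced mouse gliomas. H3K27ac marks active promoters and enhancers, and H3K4me3 marks mainly promoters. The Olig2 list of control tumours held 39201 peaks over 36.9 Mb, with a median width of 834 bp. The H3K27ac lists held 56600 peaks over 100.9 Mb in control tumours and 69365 peaks over 122.1 Mb in Olig2cKO tumours. The H3K4me3 lists held 44676 peaks over 62.4 Mb and 48885 peaks over 76.99 Mb. Each list came from 1 library of unknown depth, so every difference between genotypes is a difference between 2 libraries with no replicate check.

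Peaks of the 4 histone lists were at most 8977 to 9285 bp wide, and in each list the median score was highest for widths of 3 to 4 kb. For control H3K27ac it was 516.8 there and 86.7 at 8 kb or more, and for control H3K4me3 it was 1678 and 134.5. The named genotype-only peaks, 955 to 4764 bp wide, lay on both sides of this highest class.

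**Figure D1:**
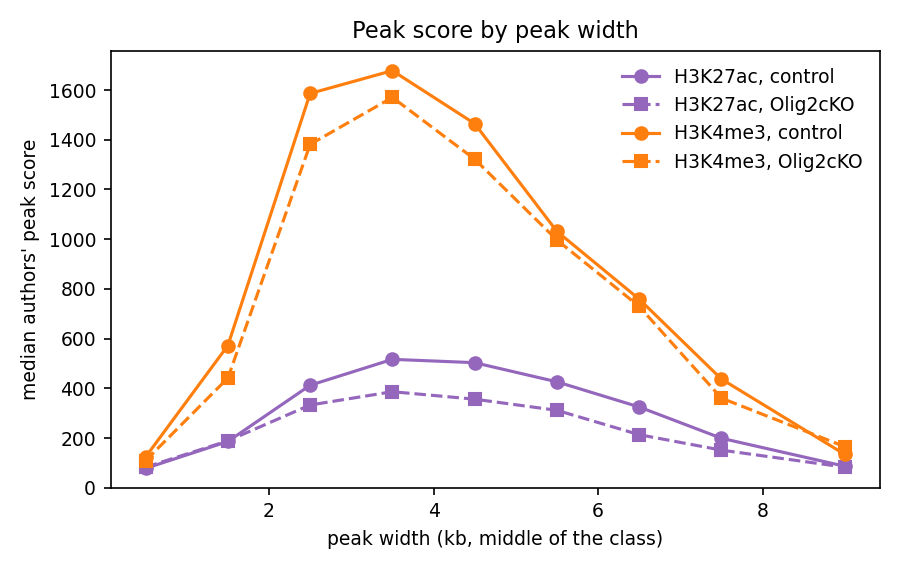
Median of the authors' peak score (y axis) by peak width (x axis, kb, middle of each width class) in the 4 histone lists; each point is the median over the peaks of 1 library in that class. The medians rise up to 3 to 4 kb, where they are 516.8 for control H3K27ac and 1678 for control H3K4me3, and fall for wider peaks.

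The H3K27ac comparison asked which acetylated regions Olig2cKO tumours share with control tumours. Of the 56600 control peaks, 46442 (82.1%, 95% interval 81.7 to 82.4) overlapped an Olig2cKO peak, and 10158 (17.9%, 17.6 to 18.3) were control-only. Of the 69365 Olig2cKO peaks, 21464 (30.9%, 30.6 to 31.3) were Olig2cKO-only. Random placement gave an overlap of 9.28% (range 8.90 to 9.68) for control peaks and 7.66% (7.36 to 8.04) for Olig2cKO peaks, and shifts of up to 1 Mb gave 12.8% and 10.6%. Genotype-only peaks were weak in their own list. The median score of control peaks was 86.7 without a partner and 215.8 with one, and that of Olig2cKO peaks was 89.1 and 238.9. The control-only share fell from 44.0% in the lowest score decile to 0.601% in the highest, and the Olig2cKO-only share from 68.9% to 1.30%. The Olig2cKO list was longer by 12765 peaks, and Olig2cKO-only peaks outnumbered control-only peaks by 11306. With lists cut to equal length the order of the shares turned, with 24.7% control-only and 23.2% Olig2cKO-only, where the counts can differ only through peaks that overlap more than 1 partner. Among the upper 50% of peaks by score, set against the whole other list, 5.7% were control-only and 10.7% were Olig2cKO-only, a comparison added after the data were seen.

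The 5 control-only H3K27ac peaks with the highest scores lay on chromosome 9 from 42188595 to 42192826 (score 1859.56), chromosome 5 from 124479735 to 124482258 (1586.41), chromosome 1 from 88329057 to 88333678 (1566.15), chromosome 3 from 55250603 to 55253626 (1229.41) and chromosome 4 from 96255922 to 96259469 (1186.5). All 5 carried an Olig2 peak, and all 5 carried H3K4me3 peaks in both genotypes. The 5 highest Olig2cKO-only peaks lay on chromosome 5 from 123588940 to 123592253 (score 1740.53), chromosome 11 from 77974866 to 77978730 (1356.63), chromosome 4 from 8307129 to 8311238 (1270.83), chromosome 3 from 121400915 to 121405678 (1230.32) and chromosome 10 from 6237171 to 6241282 (1195.5). H3K4me3 was listed in both genotypes at all 5 of these, and Olig2 at 4. These 10 peaks were 2524 to 4764 bp wide. Scores of 1000 or more were reached by 17 control-only and 19 Olig2cKO-only peaks. Scores are not scaled between libraries, and the highest decile began at 750 in the control list and 649 in the Olig2cKO list. These counts therefore do not compare the genotypes.

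**Figure D2:**
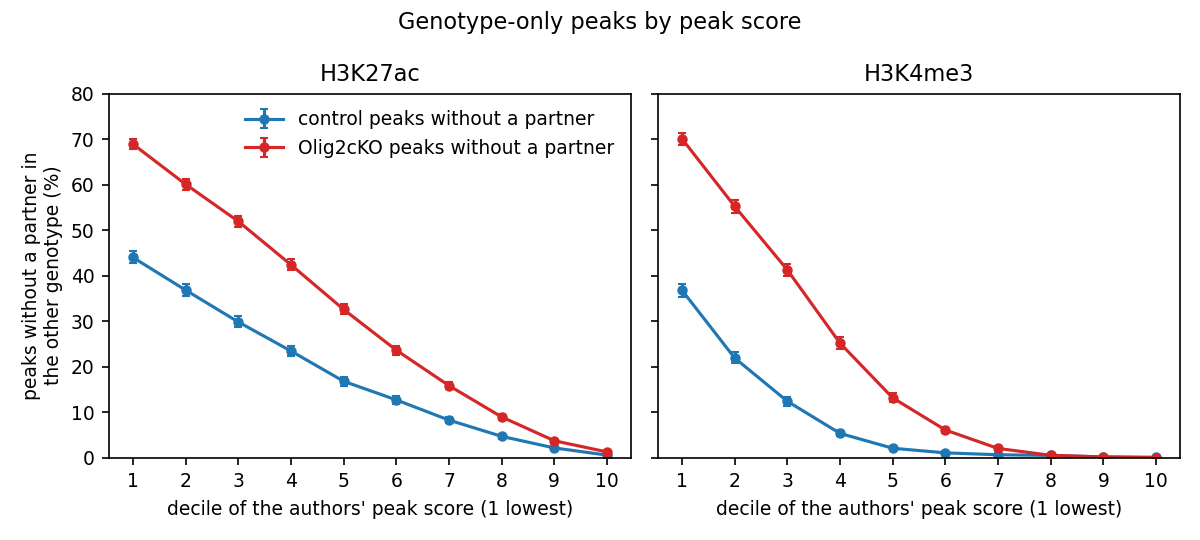
Share of peaks without a partner in the other genotype (y axis, percent) by decile of the authors' score within each list (x axis, 1 is lowest), for H3K27ac and H3K4me3; points are shares of 1 library and bars are 95% exact binomial intervals. For H3K27ac the Olig2cKO-only share falls from 68.9% to 1.30% and the control-only share from 44.0% to 0.601%.

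H3K4me3 was shared more often than H3K27ac. Of the 44676 control peaks, 41044 (91.9%, 91.6 to 92.1) overlapped an Olig2cKO peak and 3632 (8.13%, 7.88 to 8.39) were control-only. Of the 48885 Olig2cKO peaks, 10456 (21.4%, 21.03 to 21.76) were Olig2cKO-only. Random placement gave overlaps of 5.48% (5.15 to 5.84) and 4.85% (4.57 to 5.13). The control-only share fell from 36.8% in the lowest score decile to 0.134% in the highest, and the Olig2cKO-only share from 70.1% to 0.0205%. The Olig2cKO list was longer by 4209 peaks, and Olig2cKO-only peaks outnumbered control-only peaks by 6824. With lists of equal length, 10.8% were control-only and 16.7% Olig2cKO-only. In the upper 50% by score against the whole other list, 0.528% were control-only and 1.79% Olig2cKO-only.

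The 5 highest control-only H3K4me3 peaks lay on chromosome 2 from 20886698 to 20889821 (score 3142.49), chromosome 9 from 107534270 to 107537575 (2955.21), chromosome 17 from 34333771 to 34336640 (2359.25) and from 34323021 to 34325016 (2083.55), and chromosome 16 from 38090074 to 38094450 (2064.87). H3K27ac was listed at 3 of them in control tumours and at 4 in Olig2cKO tumours, where H3K4me3 was not listed, and Olig2 was listed at 4. The 5 highest Olig2cKO-only peaks lay on chromosome 10 from 99061386 to 99063666 (score 2124.05), chromosome 4 from 39756453 to 39759447 (1693.21) and from 126692785 to 126693739 (1405.76), chromosome 2 from 118379317 to 118380762 (1671.67) and chromosome 6 from 63665830 to 63667392 (1382.61). At all 5 of these, H3K27ac was listed in Olig2cKO and not in control tumours, and Olig2 was listed at 1. Over all genotype-only H3K4me3 peaks with a score of 1000 or more, 19 of 25 control-only peaks carried control H3K27ac and 12 (48.0%, 27.8 to 68.7) carried Olig2cKO H3K27ac. Of 15 Olig2cKO-only peaks, 12 carried Olig2cKO H3K27ac and 0 carried control H3K27ac. Among shared control H3K4me3 peaks of that score, 88.9% carried control and 87.4% Olig2cKO H3K27ac. Since scores are not scaled between libraries, the numbers 25 and 15 do not compare the genotypes.

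**Figure D3:**
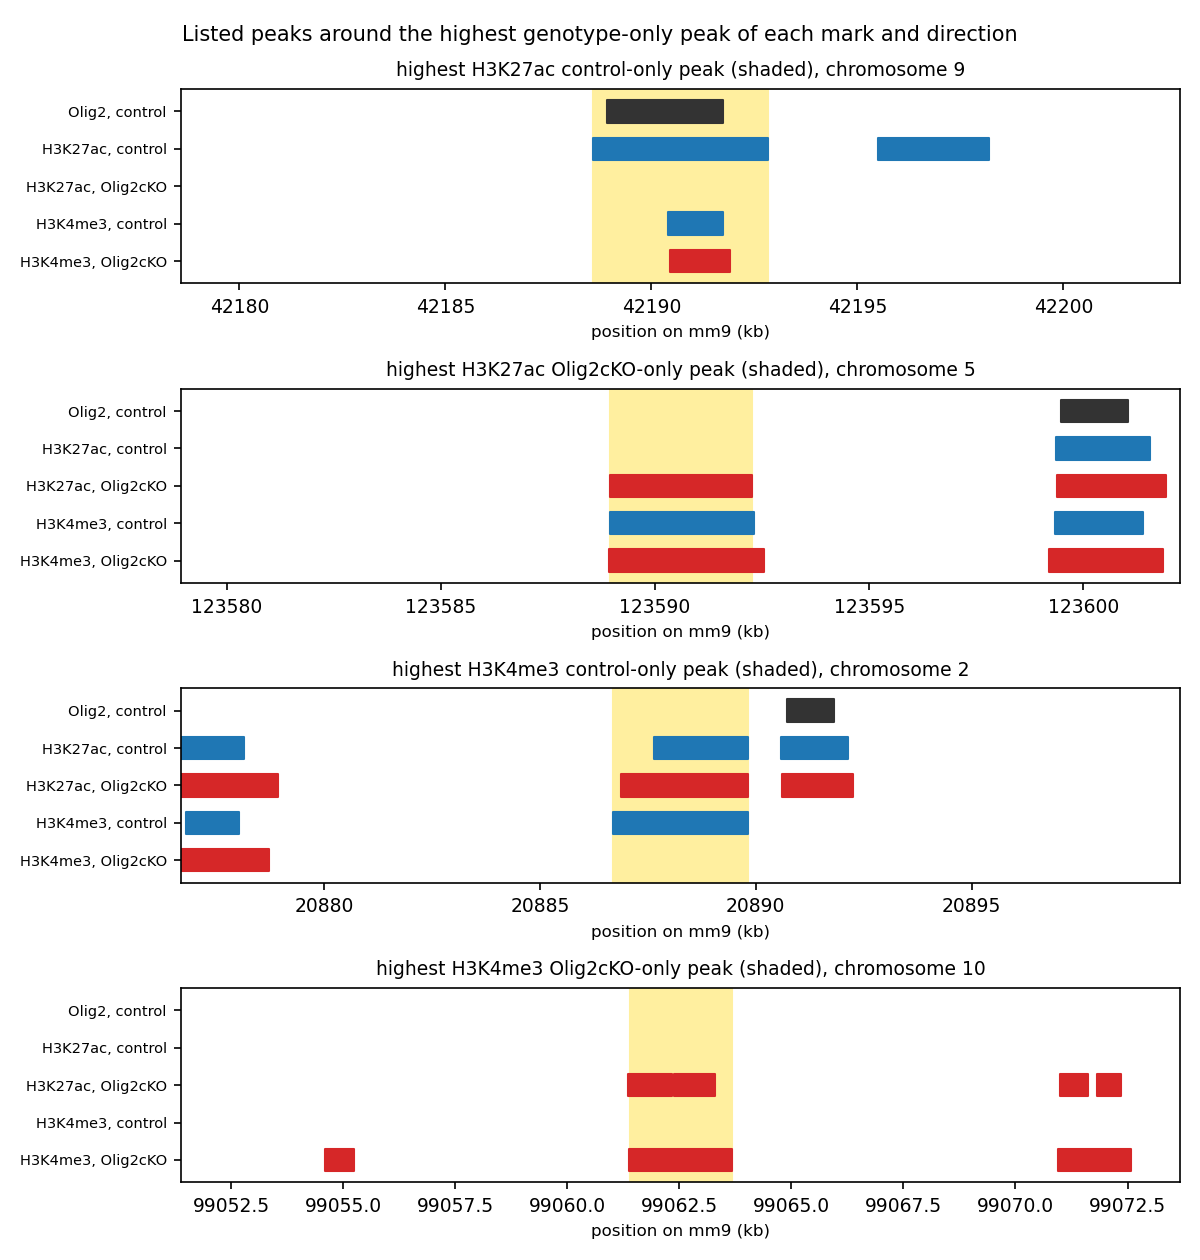
Listed peaks of the 5 libraries (rows; black for Olig2, blue for control, red for Olig2cKO) along mm9 (x axis, kb), within 10 kb of the highest genotype-only peak (shaded) of each mark and direction. At the control-only H3K4me3 peak on chromosome 2, H3K27ac is listed in both genotypes, while at the Olig2cKO-only H3K4me3 peak on chromosome 10 it is listed in Olig2cKO tumours alone.

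Shared H3K4me3 peaks were wider in the Olig2cKO list. Among 35250 peaks with exactly 1 partner, the median width was 1163 bp in control and 1353 bp in Olig2cKO tumours, the median difference (Olig2cKO minus control) was 150 bp, and 76.7% (76.3 to 77.2) were wider in Olig2cKO tumours. Among 43120 such H3K27ac pairs the median difference was 73 bp, and 57.0% (56.5 to 57.4) were wider in Olig2cKO tumours. In the narrowest decile of pairs the difference was 85 bp for H3K4me3 and -13 bp for H3K27ac. Widths can depend on the depth of each library, which is unknown, so this was not tested.

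The marks were compared with each other to see whether genotype-only peaks of both marks lay at the same sites. Control-only H3K27ac peaks that carried H3K4me3 in control tumours had no Olig2cKO H3K4me3 in 474 of 2570 cases (18.4%, 16.96 to 19.998), against 1529 of 25866 (5.91%, 5.63 to 6.21) for shared H3K27ac peaks. Olig2cKO-only H3K27ac peaks that carried H3K4me3 had no control H3K4me3 in 2131 of 5511 cases (38.7%, 37.4 to 40.0), against 3228 of 28976 (11.1%, 10.8 to 11.5). These shares are without score or width classes. Over all peaks, genotype-only H3K27ac peaks were weaker and narrower than shared ones (median 1034 against 1594 bp in control, 1040 against 1648 bp in Olig2cKO tumours). Narrow peaks have less room to overlap any H3K4me3 peak, so joint gain or loss of the marks is not shown. After all 4 histone lists were merged into 91232 regions, 23847 (26.1%) held both marks in both genotypes, 1998 held both marks in Olig2cKO tumours and neither in control tumours, and 458 the reverse. Olig2 peaks lay in 37.0% (36.7 to 37.3) of all 91232 regions. They lay in 73.8% (73.2 to 74.3) of the regions with both marks in both genotypes. The share was 21.7% (19.9 to 23.6) with both marks in Olig2cKO tumours alone, and 37.8% (33.3 to 42.4) with both in control tumours alone. Since Olig2 was mapped in control tumours alone, regions marked there can be favoured, and region widths were not matched. These shares therefore do not compare loss and gain of the marks at Olig2 sites.

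Olig2 peaks lay mostly on acetylated chromatin. Of the 39201 peaks, 27022 (68.9%, 68.5 to 69.4) overlapped control H3K27ac and 21778 (55.6%, 55.1 to 56.0) overlapped control H3K4me3. Random placement gave 6.03% (5.60 to 6.43) and 3.96% (3.53 to 4.32). Both marks were present at 18692 Olig2 peaks (47.7%), H3K27ac alone at 8330 (21.2%), H3K4me3 alone at 3086 (7.87%) and neither at 9093 (23.2%). The share on H3K27ac rose with the Olig2 score, from 44.8% in the lowest decile to 87.0% in the highest, and the share on H3K4me3 from 33.0% to 74.3%. With the upper 50% of each list, 42.6% of Olig2 peaks lay on H3K4me3. The 5 highest Olig2 peaks lay on chromosome 9 from 35112389 to 35113397 (score 2772.83), chromosome 12 from 75904717 to 75905655 (2433.04) and from 68160005 to 68161327 (2230.38), chromosome 2 from 98506283 to 98507608 (2344.47) and the mitochondrial genome from 1 to 7370 (2060.19). All 5 overlapped peaks in all 4 histone lists, the mitochondrial one included, so overlap at these highest peaks need not mean acetylated chromatin. Of the 10 highest Olig2 peaks, 7 had a peak with both edges within 300 bp in each of those lists, against 1.15% of the other peaks of the highest decile.

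Most Olig2 sites with a mark in control tumours also carried it in Olig2cKO tumours. H3K27ac was listed in both genotypes at 24627 Olig2 peaks (62.8%), in control tumours alone at 2395 (6.11%) and in Olig2cKO tumours alone at 2907 (7.42%). H3K4me3 was listed in both at 20274 (51.7%), in control alone at 1504 (3.84%) and in Olig2cKO alone at 2520 (6.43%). Of the Olig2 peaks with both marks in control tumours, 16659 (89.1%) had both in Olig2cKO tumours and 169 (0.904%) had neither. Of those with H3K27ac alone, 6952 (83.5%) still carried H3K27ac, and 1566 (18.8%) carried H3K4me3. Of the 9093 Olig2 peaks with neither mark, 1906 (20.96%) carried H3K27ac in Olig2cKO tumours.

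Control H3K27ac peaks with Olig2 were control-only less often than those without it. The shares were 2620 of 28012 (9.35%, 9.01 to 9.70) with Olig2 and 7538 of 28588 (26.4%, 25.9 to 26.9) without. Bound control peaks had a median score of 323.0 and a median width of 1762 bp, against 113.6 and 1261 bp for unbound peaks. Within score and width classes the odds ratio was 0.638 (0.605 to 0.673), against 0.288 (0.275 to 0.302) without classes. It was 0.709 (0.660 to 0.762) among distal peaks and 0.793 (0.725 to 0.868) among promoter-type peaks. The bound share was lower in 9 of 10 score deciles. In the highest decile the shares were 0.628% bound (33 of 5251, 0.433 to 0.881) and 0.244% unbound (1 of 409, 0.00619 to 1.35). These intervals overlap, so no reversal is shown there. Olig2cKO H3K27ac peaks at Olig2 sites were Olig2cKO-only in 10.4% (10.0 to 10.7) of cases and elsewhere in 46.2% (45.7 to 46.7), with an odds ratio of 0.270 (0.258 to 0.283) within classes. Olig2 sites were mapped in control tumours alone, and 68.9% of them lay on control H3K27ac. Picking Olig2cKO peaks by these sites can by itself favour peaks with a control partner. The low Olig2cKO-only share at Olig2 sites therefore does not measure an effect of Olig2.

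For H3K4me3 the direction depended on the peaks set side by side. The control-only share was 6.59% (6.28 to 6.90) of 24898 bound peaks and 10.1% (9.66 to 10.5) of 19778 unbound peaks, an odds ratio of 0.630 (0.588 to 0.674). Within score and width classes the ratio was 1.21 (1.12 to 1.30), and with control H3K27ac as a further class it was 1.03 (0.953 to 1.12), an interval that includes 1. It was 1.18 (1.03 to 1.36) among peaks without control H3K27ac and 0.964 (0.871 to 1.07) among those with it. Among Olig2cKO H3K4me3 peaks, 10.2% (9.82 to 10.6) of those with Olig2 and 32.7% (32.2 to 33.3) of those without were Olig2cKO-only, and the ratio within classes was 0.356 (0.335 to 0.378). As for H3K27ac, Olig2 sites mapped in control tumours can favour a control partner, so this ratio does not measure an effect of Olig2. With the upper 50% of each list, the control-only shares were 4.48% with and 6.51% without Olig2.

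**Figure D4:**
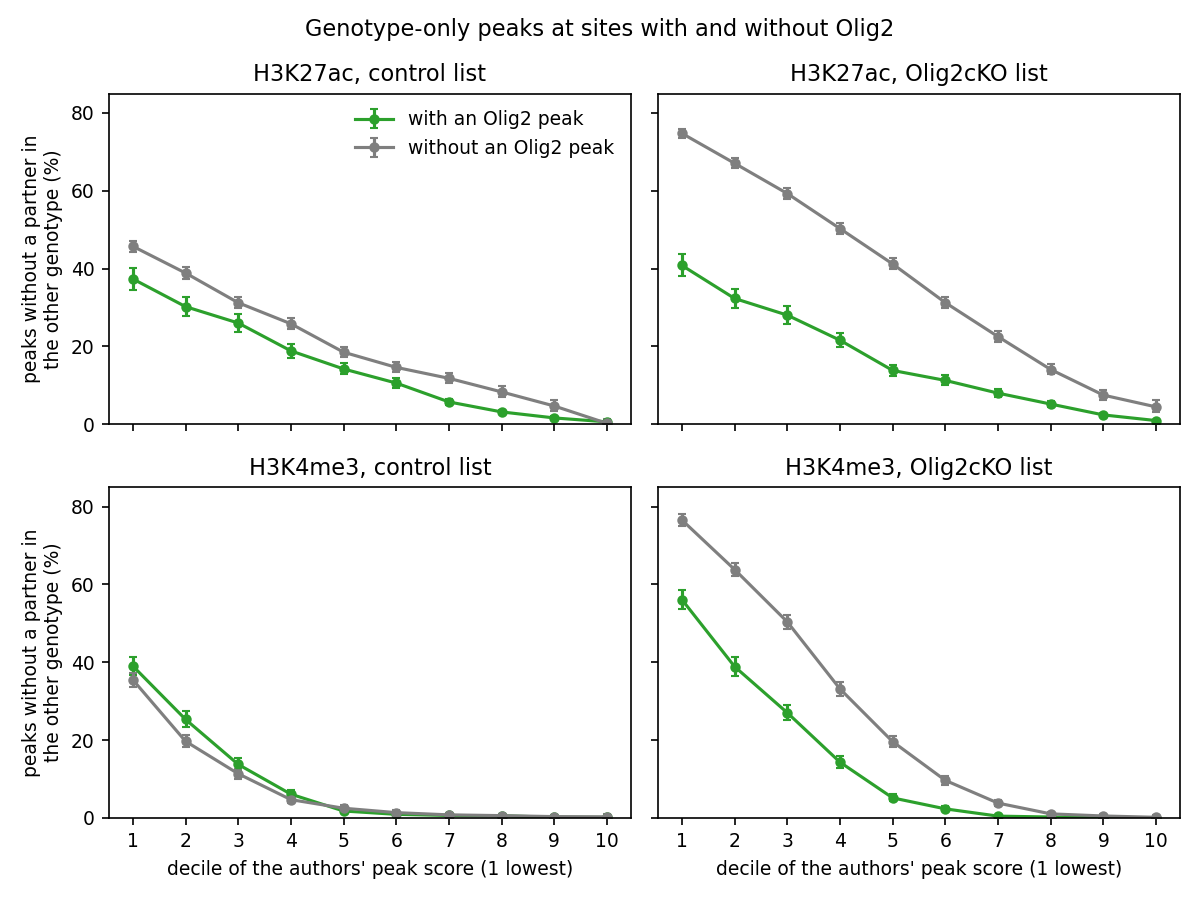
Share of peaks without a partner in the other genotype (y axis, percent) by decile of the authors' score (x axis, 1 is lowest), for peaks with (green) and without (grey) an Olig2 peak of control tumours, in each histone list; bars are 95% exact binomial intervals within 1 library. The bound share is lower in all 10 deciles of both Olig2cKO lists, though the H3K4me3 curves nearly meet in the highest deciles. Olig2 was mapped in control tumours alone, which can favour this order. For control H3K4me3 the curves cross, with a higher bound share in the 4 lowest of 10 deciles, where most control-only peaks lie. For control H3K27ac they cross in the highest decile, where the unbound share is 1 of 409 peaks and the intervals overlap.

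Distal acetylation was shared less often than acetylation at H3K4me3 sites. Of 28164 distal control H3K27ac peaks, 7588 (26.9%, 26.4 to 27.5) were control-only, against 2570 of 28436 promoter-type peaks (9.04%, 8.71 to 9.38). The odds ratio for promoter-type peaks was 0.515 (0.488 to 0.543) within score and width classes. In Olig2cKO tumours, 45.7% (45.2 to 46.3) of 34878 distal and 15.98% (15.6 to 16.4) of 34487 promoter-type peaks were Olig2cKO-only, with a ratio of 0.429 (0.412 to 0.447). With lists of equal length, 35.6% of distal and 13.9% of promoter-type control peaks were control-only.

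Stitching distal H3K27ac peaks gave 1419 domains in control and 2148 in Olig2cKO tumours, with median lengths of 21158 and 20543 bp. In control tumours 29 domains (2.04%, 1.37 to 2.92) held no Olig2cKO peak, and in Olig2cKO tumours 183 (8.52%, 7.37 to 9.78) held no control peak. With lists of equal length these counts were 61 and 51, the reverse order, and with the upper 50% of each list they were 6 and 37. The longest control domain, on chromosome 2 from 177919217 to 178008886 (89.7 kb), held 10 peaks in each genotype. The other 4 of the 5 longest, in order of length, held 8, 11, 8 and 8 control peaks and 6, 11, 7 and 4 Olig2cKO peaks. The longest Olig2cKO domain, on chromosome 12 from 103820330 to 103904372 (84.0 kb), held 9 control and 10 Olig2cKO peaks. The other 4 of the 5 longest held 5, 5, 6 and 7 control peaks and 10, 9, 8 and 11 Olig2cKO peaks. The 5 longest control-only domains lay on chromosome 7 from 29706412 to 29741436 (35.0 kb), chromosome 12 from 83469847 to 83499773 (29.9 kb), chromosome 14 from 35715571 to 35743860 (28.3 kb), chromosome 10 from 83848996 to 83876975 (28.0 kb) and chromosome 14 from 64963412 to 64989308 (25.9 kb). They held 3, 3, 1, 1 and 2 Olig2 peaks in this order. The 5 longest Olig2cKO-only domains lay on chromosome 6 from 18571300 to 18614945 (43.6 kb), chromosome 3 from 142914814 to 142954935 (40.1 kb), chromosome 15 from 68302892 to 68337834 (34.9 kb), chromosome 5 from 125501192 to 125535616 (34.4 kb) and chromosome 3 from 30641135 to 30674629 (33.5 kb). The domain on chromosome 5 held 1 Olig2 peak and the other 4 held 0. Olig2 peaks lay in 990 of all 1419 control domains (69.8%) and in 10 of the 29 control-only ones (34.5%). They lay in 1268 of all 2148 Olig2cKO domains (59.0%) and in 41 of the 183 Olig2cKO-only ones (22.4%). Domain length and strength were not matched, and Olig2 was mapped in control tumours alone. These shares therefore do not show that genotype-only domains are poor in Olig2.

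Genotype-only peaks were spread over the genome, and windows rich in them held many peaks of both genotypes. Control-only H3K27ac peaks fell in 2096 windows of 1 Mb with a median of 4, and Olig2cKO-only peaks in 2338 windows with a median of 9. The window with most control-only H3K27ac peaks, on chromosome 4 from 137000001 to 138000000, held 20 of them among 65 control peaks, and the other 4 of the 5 windows held 17 to 19. The windows with most Olig2cKO-only H3K27ac peaks held 32 each, on chromosome 10 from 93000001 to 94000000 and on chromosome 17 from 50000001 to 51000000. In the latter, H3K27ac peaks numbered 24 in control and 51 in Olig2cKO tumours. Chromosome 4 from 138000001 to 139000000 was among the 5 windows in both directions, with 19 control-only and 27 Olig2cKO-only peaks. For H3K4me3, chromosome 8 from 19000001 to 20000000 held most control-only peaks (12, with 24 control and 12 Olig2cKO peaks), and chromosome 4 from 149000001 to 150000000 most Olig2cKO-only peaks (22, with 43 control and 58 Olig2cKO peaks).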

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

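The median peak width of whole lists moved in opposite directions in the 2 marks between genotypes, but that of matched peaks did not. Over whole lists it fell by 41 bp for H3K27ac, from 1475 bp in the control list to 1434 bp in the Olig2cKO list, and rose by 107 bp for H3K4me3, from 1104 to 1211 bp. Among peaks with exactly 1 partner the marks moved the same way, with a median difference (Olig2cKO minus control) of 73 bp over 43120 H3K27ac pairs and 150 bp over 35250 H3K4me3 pairs. For H3K27ac, median widths were larger in the Olig2cKO list both with a partner (1648 against 1594 bp) and without one (1040 against 1034 bp). The narrower peaks without a partner made up 30.9% of the Olig2cKO list and 17.9% of the control list, which lowers the whole-list median of Olig2cKO. The difference between the marks was not tested, since each group had 1 library.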

How the results depend on the processing

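The 14 shares and counts were each recomputed under the alternatives that applied to them. In all there were 7 alternatives fixed before the data were examined and 2 added after the data were seen, which gave 92 values. Of these, 30 stayed within the 95% interval of the reported share, or within 1.5 times the reported count, and 62 moved further. Of 39 orders compared (control-only against Olig2cKO-only for each mark and for domains, bound against unbound for each mark, promoter-type against distal), 37 kept their direction and 2 turned, both with lists of equal length: H3K27ac peaks and domains. These orders are of shares without score or width classes. The gap between Olig2cKO-only and control-only peaks is the gap in list length plus the difference in shared peaks (control minus Olig2cKO). For H3K27ac, 12765 and -1459 gave 11306, and for H3K4me3, 4209 and 2615 gave 6824. At equal length only a difference in shared peaks remains, which comes from peaks that overlap more than 1 partner. Neither the turn for H3K27ac nor the order kept for H3K4me3 measures gain or loss of the mark on its own. Unless stated, the cause of a move was not tested. No replicate could be left out, since each group had 1 library. The promoter window and distance alternatives for gene lists were not run. No paired analysis was possible because each group had 1 library.

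With lists of equal length, the control-only and Olig2cKO-only shares were 24.7% and 23.2% for H3K27ac and 10.8% and 16.7% for H3K4me3. The control-only share was 13.7% at bound and 35.5% at unbound H3K27ac peaks, 8.70% and 13.4% at bound and unbound H3K4me3 peaks, and 35.6% at distal and 13.9% at promoter-type peaks. Domains without a partner numbered 61 in control and 51 in Olig2cKO tumours.

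With the upper 50% of each list by score, the control-only and Olig2cKO-only shares were 19.4% and 32.8% for H3K27ac and 5.63% and 18.2% for H3K4me3. Olig2 lay on H3K27ac at 66.2% and on H3K4me3 at 42.6% of its peaks. The control-only share was 11.1% at bound H3K27ac peaks, 4.48% and 6.51% at bound and unbound H3K4me3 peaks, and 25.9% at distal and 10.8% at promoter-type peaks. Domains without a partner numbered 6 and 37. With the upper 50% of a list against the whole other list, added after the data were seen, the control-only and Olig2cKO-only shares were 5.7% and 10.7% for H3K27ac and 0.528% and 1.79% for H3K4me3. The control-only share was then 3.56% and 10.7% at bound and unbound H3K27ac peaks and 0.418% and 0.747% at bound and unbound H3K4me3 peaks.

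With an overlap of 50% of the shorter peak, 18.4% of control and 31.5% of Olig2cKO H3K27ac peaks and 8.42% of control H3K4me3 peaks had no partner. Olig2 lay on H3K27ac at 65.8% and on H3K4me3 at 51.0% of its peaks, and the control-only share was 9.001% at bound H3K27ac peaks, 7.68% and 9.03% at bound and unbound H3K4me3 peaks and 27.6% at distal peaks. With peaks up to 1 kb apart counted as shared, which can only add partners, the control-only and Olig2cKO-only shares were 15.6% and 28.4% for H3K27ac and 6.89% and 19.9% for H3K4me3. Olig2 then lay on H3K27ac at 70.6% and on H3K4me3 at 57.5% of its peaks. The control-only share was 7.40% and 24.3% at bound and unbound H3K27ac peaks, 5.34% and 9.25% at bound and unbound H3K4me3 peaks, and 25.1% at distal and 6.82% at promoter-type peaks.

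With peaks within 1 kb merged, the control-only share of H3K27ac was 17.3% and the Olig2cKO-only share of H3K4me3 was 22.1%. The control-only share was 8.08% at bound H3K27ac peaks, 10.7% at unbound H3K4me3 peaks and 7.55% at promoter-type peaks, and 111 Olig2cKO domains had no partner. With a stitching distance of 5 kb, 7 control and 30 Olig2cKO domains had no partner. On numbered chromosomes alone, all 14 values stayed within those limits.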

Other observations

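All the tests in this part were chosen after the result they bear on had been seen. Shared and genotype-only H3K27ac peaks differed in their distance to Olig2. The median distance from the middle of an H3K27ac peak to the middle of the nearest Olig2 peak was 0.879 kb for shared control peaks, 9.87 kb for control-only peaks and 14.7 kb for Olig2cKO-only peaks. More than 50 kb separated 6.69%, 12.2% and 18.2% of these peaks from Olig2. Genotype-only peaks were weaker than shared ones, and Olig2 was mapped in control tumours alone, so these distances do not compare the genotypes. Within merged regions, 3036 with H3K4me3 in both genotypes had H3K27ac in Olig2cKO tumours alone, of which 36.3% (34.6 to 38.0) held Olig2. Another 1843 had H3K27ac in control tumours alone, of which 52.3% (49.9 to 54.6) held Olig2. Mapping Olig2 in control tumours alone can favour regions acetylated there, and region widths were not matched. These shares of merged regions therefore do not compare loss and gain of H3K27ac at Olig2 sites. Peak numbers were higher in Olig2cKO than in control tumours for both marks on chromosomes 1 to 19 and X. On Y they were 48 and 49 for H3K27ac and 61 and 63 for H3K4me3, and on the mitochondrial genome they were equal.

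Control H3K27ac peaks with Olig2 had an Olig2cKO partner more often than those without. The odds ratio was 0.638 (0.605 to 0.673) within score and width classes, and 0.740 (0.699 to 0.782) with H3K4me3 as a further class. Strength, width and H3K4me3 as divided into these classes thus did not account for the whole difference. Peaks inside a class still differ in strength, the highest score class running from 750 to 3117, and H3K4me3 was classed only as present or absent. These ratios therefore cannot exclude peak strength, width or H3K4me3 as the whole cause. A biological difference between the genotypes, a difference in library depth and the mapping of Olig2 in control tumours alone stay open and were not tested.

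No histone peak reached 10 kb, the widest of each list measuring 8977 to 9285 bp. The median score rose with width up to 3 to 4 kb and then fell, and in the 4 lists the ratio of the median score at 8 kb or more to that at 3 to 4 kb was at most 0.215. H3K27ac peaks at most 200 bp apart formed 39 runs longer than 10 kb (17 in control, 22 in Olig2cKO tumours). If such a run is taken as 1 region, these runs argue against H3K27ac regions that end below 10 kb. Whether the gaps inside a run carry the mark was not tested. For H3K4me3 there were 5 such runs (1 and 4), too few to tell whether H3K4me3 regions end below 10 kb. A first limit of more than 0 runs per list was met by both marks, and the limit of 10 per list used here for both, which H3K27ac alone met, was set after these counts were seen. A candidate explanation is a background taken from the 10 kb around each peak in the same library, which would lower the score of wide regions and could leave strong, wide regions out of a list, though no caller setting in the sources used here settles it.

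The 10 highest Olig2 peaks all lay under peaks of all 4 histone lists, and 7 of them had a peak with both edges within 300 bp in each list. This share was 70% (34.8 to 93.3), against 1.80% (1.31 to 2.40) of 2505 other peaks of the highest decile that were in all 4 lists. Control H3K27ac peaks at the 10 had a median width of 1421.5 bp, against 2260 bp for the rest of the highest decile. Narrower histone peaks match the edges of an Olig2 peak more easily, and width was not matched. The share therefore cannot decide for or against Olig2 at strongly acetylated sites. A candidate explanation for the highest Olig2 peaks outside the mitochondrial genome is reads piling up on collapsed repeats in each library. At the 5 highest Olig2 peaks, the control H3K27ac peak ranked 4, 15, 45, 119 and 13998 by score among 56600, the last on the mitochondrial genome. Without the 306 Olig2 peaks matched in this way, 68.7% of Olig2 peaks lay on control H3K27ac.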
